A study of Drosophila melanogaster with 3 samples.

How the data were processed

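Chromatin immunoprecipitation with an anti-GFP antibody was carried out on whole prepupae of a transgenic line, with chromatin sheared by sonication, per the labels. The 3 samples were labelled as biological replicates 1, 2 and 3 of 1 group. Control alignments entered the authors' peak calls, per the file lists deposited with the samples, and control libraries were not analysed here.

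The files used were lists of peaks. Per the deposited file lists, each replicate's list was called on that replicate's alignment with a control, a pooled list on the alignments of all 3, and the optimal list was thresholded by irreproducible discovery rate from these. The aligner, the peak caller and their versions are not given in the sources used here. Each peak carries the authors' signal value, whose scale is not stated and differs between lists, and a value read from the layout as the −log10 of the q-value in the authors' deposited lists. In the optimal dm6 list 68.2% of peaks share its highest −log10 value of 3.84, so peaks were ranked by the authors' signal. The relaxed lists hold 30000 peaks each, background included. All 5048 optimal dm6 peaks were rows of the pooled list, and no pooled peak at or above the lowest optimal signal was left out. The lists hold no read counts, so the depth per sample is unknown and only the agreement of 3 replicates bears on precision. No more than 1 interval was identical between any 2 replicates' lists, so they were counted as separate samples.

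Positions are on dm6, counted from 1. Gene models were taken from the Ensembl annotation of release 115 (BDGP6.54) and sequence from the NCBI copy of the same assembly, and every dm6 peak lay within the length of its chromosome. The dm3 optimal list was used only for counts, signal values and positions as given, with no conversion of coordinates. The other dm3 lists were not used here.

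The design, the gene lists, the motifs and the rule for named genes were fixed before the data were examined. The rule took the 25 optimal peaks of highest signal with the nearest protein-coding TSS, ouib and every gene of ecdysone synthesis with or without a peak, the 4 members of each other list with the highest signal at a promoter peak, and the 5 8-mers of lowest p. EcR, usp, br, Eip74EF, Eip93F and ftz-f1 fall outside it and were named after their values were seen. The same holds for Hr3, Hr4, Hr38, Hr39, Eip78C, Kr-h1, Snap25, RpL15 and RpL38. Listed symbols were matched to the annotation through synonyms, so that phm is phtm, and sean, don and poils were not matched. To compare replicates, each was reduced to its 5048 best peaks, and its signal was divided by their median.

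Overlap between replicates (1 bp or more) was set against 100 sets of intervals placed at random on the same chromosomes. Summits within 500 bp of the TSS of a protein-coding gene were called promoter summits, and other summits were assigned in the order coding exon, 5' UTR, 3' UTR, intron and intergenic; 1000 random sets gave the reference. Gene lists were compared with all other protein-coding genes by Fisher's exact test on summits within 1000 bp of a TSS, with Benjamini-Hochberg adjustment over 18 lists. Any annotated TSS of a gene sufficed, and neither the number of TSSs nor gene length was adjusted for. tRNA genes were to be compared with other tRNA genes, but the list holds all of them, so they were set against protein-coding genes. Motifs on either strand were counted in windows of 200 bp and 8-mers in windows of 100 bp, against windows centred 1000 bp to each side, and 8-mers in fewer than 10 summit windows were left out. Signal at promoters was tested by 100000 resamples of the difference of medians. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

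The tests were tried on simulated data. With ribosomal protein genes given peaks at 50% and all other coding genes at 18%, the list test over 13945 genes called the ribosomal protein list in 100 of 100 simulations and called 3 of 1600 unchanged lists. Genes were given peaks independently, so clusters of neighbouring genes were not simulated. An 8-mer written into 150 windows was recovered among 19502 tested, and 0 of 19476 8-mers were called without it. Both sets of windows came from random positions, so this simulation did not cover the difference in GC content between summits and flanks. Positions made to give 38.0% at promoters measured 38.2%.

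Alternatives covered the overlap rule, the number of peaks, the promoter and gene windows, the 500 strongest peaks, peaks found in all 3 replicates, matched random positions, other lengths of sequence, and each replicate left out in turn. For the optimal peaks, the gene lists and the signal at promoters, leaving out a replicate meant keeping the optimal peaks that overlap a best peak of both others, so that the support asked of a peak changed too and the optimal list and its signal still rest on all 3.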

Results

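Chromatin immunoprecipitation followed by sequencing was carried out with an antibody against GFP on whole Drosophila melanogaster prepupae of mixed sex that carried Ouib fused at its C terminus to GFP. Ouib (ouija board, CG11762) is a zinc-finger protein with a ZAD domain, known from the prothoracic gland, the endocrine tissue that makes the steroid hormone ecdysone. The series held 1 group of 3 biological replicates, so no comparison between conditions was made. The peak lists give no read counts, and the depth of each library is unknown. The authors' list of optimal peaks on the dm6 build held 5048 peaks with a median width of 396 bp. Each replicate's own list held 30000 peaks, weak background peaks included.

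The first question was where in the genome the signal of the GFP precipitation was strongest. The strongest peak lay 96 bp upstream of the start of CG14100 (FBgn0036889) on chromosome 3L from 19590444 to 19590784. Its signal was 12.3 ± 0.896 times (SD, n = 3) the median of each replicate's 5048 best peaks. The next lay 53 bp upstream of Ugalt (FBgn0024994), which encodes a nucleotide sugar transporter, on chromosome X from 2703710 to 2704048, at 11.7 ± 0.837 times. The third lay in an intron of ush on chromosome 2L from 480908 to 481272, 1370 bp upstream of the nearest coding gene start, that of cbt (FBgn0043364), at 10.5 ± 1.36 times. Of the 25 strongest peaks, 12 had their summit at a promoter, 9 in an intron and 4 between genes.

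Promoter peaks among these 25 included that of Chro (FBgn0044324), a chromatin protein of interbands, on chromosome 3L from 22878731 to 22879070, at 9.33 ± 1.04 times the replicate median (SD, n = 3). They also included PNPase, which encodes a mitochondrial RNA-degrading enzyme, at 9.96 ± 0.446 times, and mRpL41, a mitochondrial ribosomal protein gene, at 9.21 ± 0.827 times. Hsp27, a small heat shock protein gene, reached 8.38 ± 0.133 times with a summit 161 bp upstream of its start. The other promoter peaks were nearest to CenG1A, CG31145, Art3, Tcs5, CG18549 and CG13921. Intronic peaks lay within CG11050, Lk6, CG32772, osa, CG9663, CG12769 and Trl, and the peak nearest to HmgZ lay in a stretch annotated to both HmgD and HmgZ. osa encodes a subunit of a chromatin remodelling complex, and Trl encodes GAGA factor. The intergenic peaks were nearest to CG4004, CG31668, CG13323 and CG43245, with the TSS of CG13323 11923 bp away. All 25 ranked among the 100 best of every replicate, and the lowest rank of any in a replicate was 46. They were picked by signal in the pool of these same replicates, which favours high ranks in each.

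**Figure D1:**
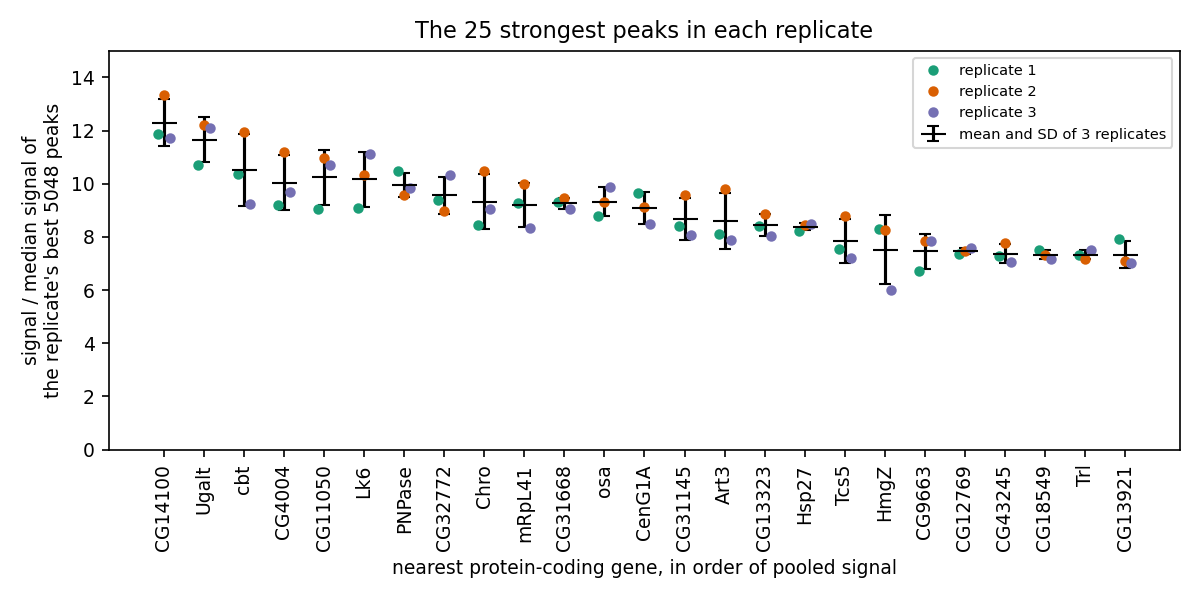
Signal of the 25 strongest optimal peaks in each replicate, divided by the median signal of that replicate's 5048 best peaks (y axis), by nearest protein-coding gene (x axis). Dots are replicates, and bars are the mean and SD of 3; means run from 12.3 at CG14100 down to 7.33 at CG13921.

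The replicates shared most of their strong peaks. Of the 5048 best peaks of 1 replicate, 77.6% were shared between replicates 1 and 2, 74.6% between replicates 1 and 3, and 76.6% between replicates 2 and 3. Intervals placed at random on the same chromosomes were shared at 2.79% on average and at most 3.18% (permutation test, one-sided, p = 0.01, the smallest that 100 placements can give). Peaks drawn at random from the same replicate's whole list were shared at 19.7%, a comparison chosen after seeing the data. Of the optimal peaks, 3350 overlapped one of the best peaks of all 3 replicates, 1195 of 2, 472 of 1 and 31 of none. All 500 of the strongest optimal peaks were among those found in all 3. The optimal list came from the pool of these same replicates and was thresholded on their agreement. Its recovery in them was favoured by that selection and is not independent evidence of agreement. Across the optimal peaks, Spearman's rho of the signal was 0.742 for replicates 1 and 2, 0.736 for 1 and 3 and 0.750 for 2 and 3; peaks are not independent replicates.

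Summits lay at promoters more often than chance placed them, and were nearly absent from coding exons. Of the optimal summits, 1695 (33.6%) lay within 500 bp of the TSS of a protein-coding gene, against 11.4% of random positions (permutation test, one-sided, p = 0.001, the smallest that 1000 placements can give). The share was 34.4% ± 0.828 (SD, n = 3) for the replicates' best peaks and 51.4% for the 500 strongest optimal peaks. Away from promoters, 5 summits (0.0991%) lay in a coding exon, against 14.1% of random positions, and 31 (0.614%) in a 3' UTR, against 4.53%. Introns held 2254 summits (44.7%, random 39.3%), and intergenic sequence held 1040 (20.6%, random 30.03%). These random positions were not matched on GC content. In a count chosen later, 17.2% of random positions lay in coding sequence, promoters included, and 4.89% when weighted to the summits' GC content.

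**Figure D2:**
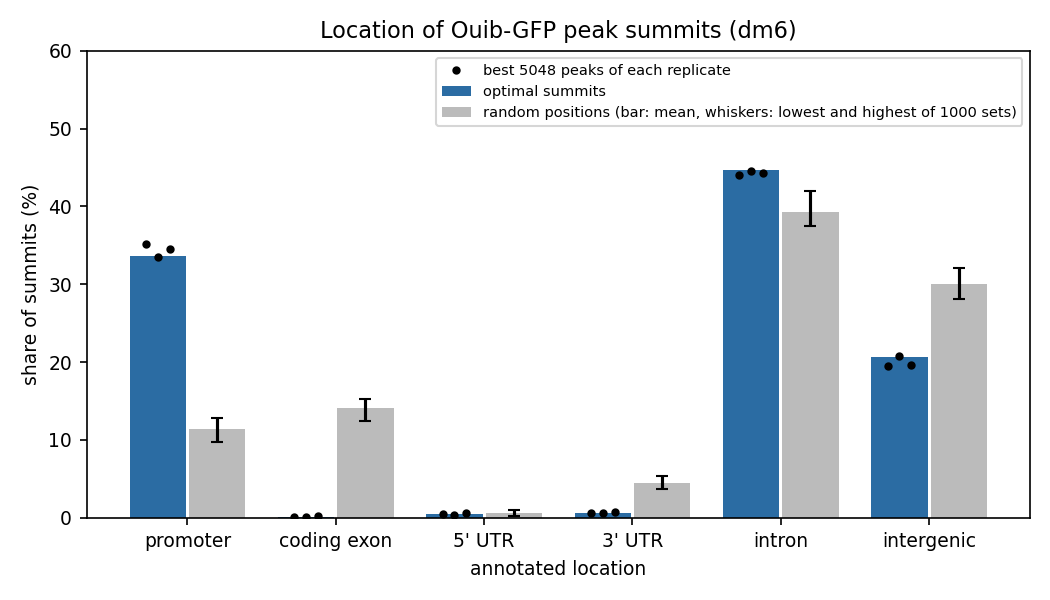
Share of summits in percent (y axis) by annotated location (x axis), for the optimal peaks (blue bars), each replicate's 5048 best peaks (dots) and 1000 sets of random positions (grey bars, mean with lowest and highest). Promoters hold 33.6% of the optimal summits and 11.4% of random positions, and coding exons 0.0991% and 14.1%.

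Peaks at promoters were somewhat stronger than the others. The authors' signal had a median of 108.4 at promoters and 98.8 elsewhere, a difference of 9.53 and a ratio of 1.10 (permutation test, two-sided, p = 7e-05). With only the optimal peaks found in both replicates 2 and 3, the difference was 15.2 (permutation p = 1e-05). In each replicate's own list the ratio of medians was 1.06 in replicate 1 (permutation p = 0.00308), 1.10 in replicate 2 (permutation p = 1e-05, the smallest that 100000 resamples can give) and 1.03 in replicate 3, which did not pass (permutation p = 0.0572).

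The genes of ecdysone synthesis, the pathway in which Ouib is known to act, did not differ detectably from other genes in promoter peaks. Of 10 genes, 1 (10%, 95% Wilson interval 1.79% to 40.4%) had an optimal summit within 1000 bp of a TSS, against 18.1% of other protein-coding genes (Fisher's exact test, two-sided, adjusted p = 1). That gene was shd (FBgn0003388), which encodes the last enzyme of the pathway, outside the gland. Its summit lay 650 bp from a TSS on chromosome 3L at 14613808, with a signal of 0.715 ± 0.459 times the replicate median (SD, n = 3). The count fell to 0 of 10 in the best peaks of replicate 1, with peaks found in all 3 replicates, with those found in both replicates 1 and 3 or both 1 and 2, with a window of 500 bp and among the 500 strongest peaks. nvd, spo, spok, sro, Cyp6t3, phtm (phantom), dib, sad and GstE14 had none. The nearest optimal summit was 4.34 kb from a TSS of sad and 7.98 kb from one of sro. It was 38.6 kb away for phtm, 891.4 kb for spok and 1446 kb for nvd. Distances as wide as the last 2 were rare among listed genes but not particular to this pathway. On chromosome 3L, which also holds nvd, the nearest optimal summit was 1195.3 kb from a TSS of Snap25 and 4388.4 kb from one of RpL15. The tagged gene itself, ouib (FBgn0037618, chromosome 3R from 8725479 to 8726730), had no optimal summit within 1000 bp of its TSS, and the nearest was 6.46 kb away.

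spok (spookier, FBgn0086917, chromosome 3R from 3322810 to 3354486, plus strand) is the gene through which Ouib is known to act. The sequence TATTATTTAG, recalled as part of the element in its promoter, occurred once in the 1000 bp upstream of the gene, from 3322648 to 3322657. No optimal or pooled peak had its summit within 5 kb of it. The list of replicate 2 held 1 peak there, at rank 21406, and those of replicates 1 and 3 held none. The same sequence occurred 973 times on the main chromosomes. The windows of 200 bp at optimal summits held it in 12 cases (0.238%), against 0.129% of flanking windows (Fisher's exact test, two-sided, adjusted p = 0.197) and 0.248% of random positions matched on GC content and distance class from a TSS (adjusted p = 1). The prothoracic gland was a small part of each whole animal, and signal from it alone cannot be told from these lists.

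Genes of 3 lists had peaks at their promoters more often than other genes, and those of 2 lists less often, among 18 lists. Ribosomal protein genes led, with 49 of 93 (52.7%) against 17.8% of other coding genes (Fisher's exact test, two-sided, adjusted p = 7.20e-13). The share in the replicates' best peaks was 52.3% ± 1.64 (SD, n = 3). RpS19b had a signal of 3.36 ± 0.432 times the replicate median, RpL32 2.19 ± 0.629, RpS27 2.15 ± 0.270 and RpL7 2.00 ± 0.327. The summit counted for RpS19b lay 905 bp from its TSS, and that for RpL32 182 bp, RpS27 18 bp and RpL7 34 bp. Among the 500 strongest peaks the list lay 1.92 percentage points below other genes (difference -1.92, exact test, adjusted p = 0.982). Ribosomal protein genes were listed beforehand as an abundant housekeeping class that often draws nonspecific signal. Control libraries were not analysed here, so such signal cannot be told from binding of Ouib.

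Ecdysone response genes, which the hormone switches on or which carry its signal, had peaks at 15 of 31 promoters (48.4%, Fisher's exact test, two-sided, adjusted p = 0.000654). A gene counted with a summit near any of its annotated TSSs, some of them inside the gene. The number of TSSs per gene was not adjusted for, so genes with many had more chances to count. E23, an ABC transporter gene, stood at 3.73 ± 0.270 times the replicate median (SD, n = 3) and hid, a cell death gene, at 3.29 ± 0.655. Eip75B, which encodes a nuclear receptor, stood at 2.26 ± 0.366, with 11 optimal summits in the gene or within 1000 bp of it, and Ldh at 1.73 ± 0.278. Other members with a promoter peak included EcR and usp, the partners of the ecdysone receptor, and br, Eip74EF, Eip93F and ftz-f1. The call was lost with only the optimal peaks found in both replicates 1 and 3 (29.0% of the list and 13.4% of other genes, exact test, adjusted p = 0.0870) and among the 500 strongest peaks (2 of 31 genes, ratio to other genes 2.17 against 2.69 with all peaks, adjusted p = 0.850).

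Genes of chromatin architecture had peaks at 7 of 15 promoters (46.7%, Fisher's exact test, two-sided, adjusted p = 0.0370). Chro, M1BP (3.40 ± 0.687), Cp190 (2.73 ± 0.669) and Trl (2.72 ± 0.573) had the strongest. With only the optimal peaks found in both other replicates, the call was lost without replicate 1 (ratio to other genes 2.46, exact test, adjusted p = 0.100) and without replicate 2 (ratio 2.48, adjusted p = 0.0957), against a ratio of 2.59 with all peaks. It was also lost with peaks found in all 3 replicates (ratio 2.69, exact test, adjusted p = 0.0772) and with a window of 5000 bp (ratio 1.45, adjusted p = 0.381). It held with a window of 500 bp (ratio 3.15, exact test, adjusted p = 0.0122) and, alone of the lists, among the 500 strongest peaks (4 of 15 genes, ratio 9.02, adjusted p = 0.0148).

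Replication histone genes had no peak at any of 111 promoters (Fisher's exact test, two-sided, adjusted p = 3.57e-09). These genes lie in repeated copies, and whether reads could be placed there was not measured, so the count of 0 cannot be read as a lack of binding. The copies were counted separately, so the p-value treats them as independent. Genes for tRNA had an optimal summit near 29 of 290 (10%) against 18.1% of coding genes (exact test, adjusted p = 0.000868), with tRNA:Tyr-GTA-1-8, tRNA:Tyr-GTA-1-7, tRNA:Val-TAC-1-1 and tRNA:His-GTG-1-2 near the strongest peaks. Both genes for tyrosine tRNA share 1 peak, and clustered genes were counted separately. In the replicates' best peaks the share for tRNA genes was 13.1%, 7.24% and 17.6%, the last close to that of coding genes. The difference for tRNA genes turned to 1.21 percentage points above coding genes with a window of 5000 bp (exact test, adjusted p = 0.801).

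Regulators of the prothoracic gland had peaks at 10 of 26 promoters (38.5%), which did not pass after adjustment (Fisher's exact test, two-sided, adjusted p = 0.0514). Keap1 stood at 4.67 ± 1.051 times the replicate median (SD, n = 3), at a summit 948 bp from a TSS. A weaker optimal summit lay 78 bp from one. cnc, its partner in oxidative stress, stood at 1.80 ± 0.158 and Mad at 1.28 ± 0.236. Eip75B, br and ftz-f1, each with a promoter peak, belong both to this list and to that of ecdysone response, so the 2 lists are not separate. With a summit anywhere in the gene body or within 1000 bp of it, the list passed (exact test, adjusted p = 0.000206). A longer gene has more room for a summit, and gene length was not adjusted for. The list did not pass with a window of 500 bp (6 of 26, exact test, adjusted p = 0.395) or among the 500 strongest peaks (1 of 26, adjusted p = 0.982). Nor did it with 1 replicate left out (exact test, adjusted p = 0.0784 to 0.187). Heat shock genes had peaks at 7 of 20 promoters (exact test, adjusted p = 0.146), the strongest at Hsp27, Hsc70-5, Hsp26 and Hsp83. The list passed with the peaks found in both replicates 1 and 2 (exact test, adjusted p = 0.0413). Hsp22 and Hsp67Bc were both counted through 1 summit, on chromosome 3L at 9373454. Mitochondrial ribosomal protein genes had them at 18 of 70 (exact test, adjusted p = 0.176), led by mRpL41, mRpS23, mRpS10 and mRpL23. The peak at mRpS23 is the one nearest to CenG1A, and that at mRpS10 the one nearest to Art3.

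None of the lists of tissue markers passed with a window of 1000 bp around the TSS (Fisher's exact test, two-sided). Salivary glue genes had 0 of 16 (exact test, adjusted p = 0.170) and testis and germline markers 0 of 19 (adjusted p = 0.0797). Cuticle genes had 1 of 30, kkv (exact test, adjusted p = 0.0797), and developmental regulators 2 of 33, so and N (adjusted p = 0.176). Neuron markers had 2 of 20, elav and Syx1A (exact test, adjusted p = 0.720), muscle markers 3 of 20, Zasp52, sls and Tm1 (adjusted p = 1), and fat body markers 2 of 15, bmm and Adh (adjusted p = 1). Proteasome genes had 4 of 32, Rpn5, Rpn3, Prosbeta2 and Rpn8 (exact test, adjusted p = 0.691), and ZAD zinc-finger genes 2 of 15, M1BP and trem (adjusted p = 1). With a window of 5000 bp, salivary glue genes (exact test, adjusted p = 0.00455) and cuticle genes (adjusted p = 0.0257) had peaks less often than other genes. With gene bodies, salivary glue genes (exact test, adjusted p = 0.0354), cuticle genes (adjusted p = 0.0135) and testis and germline markers (adjusted p = 0.0175) did. Gene length was not adjusted for there. Many glue and cuticle genes lie in clusters, such as Eig71Ea to Eig71Eg on chromosome 3L from 15649126 to 15658149. Neighbours were counted separately, so these tests treat genes that share sequence as independent. Developmental regulators did with the optimal peaks found in both replicates 1 and 2 (exact test, adjusted p = 0.0379).

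**Figure D3:**
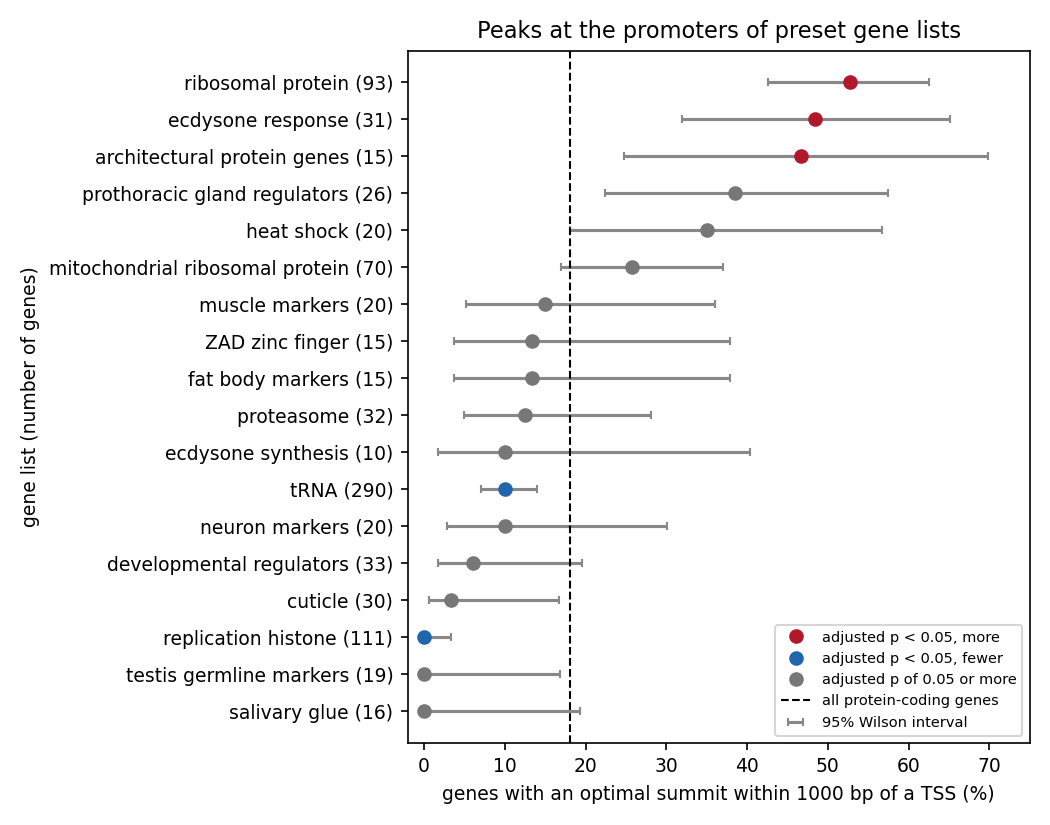
Share of genes of each preset list with an optimal summit within 1000 bp of a TSS in percent (x axis), by list with its number of genes (y axis). Bars are 95% Wilson intervals, and the dashed line is the 18.1% of all protein-coding genes; ribosomal protein genes stand at 52.7% and replication histone genes at 0%.

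Summits lay in AT-rich sequence. The windows of 200 bp at optimal summits had a mean GC content of 34.4%, and the flanking windows 42.1%. The TATA box TATAAAA was in 18.03% of summit windows and 9.20% of flanks (Fisher's exact test, two-sided, adjusted p = 9.00e-52). The replication element TATCGATA, bound by Dref and BEAF-32, was in 1.43% and 0.545% (exact test, adjusted p = 3.40e-07), and GGTCACAC, bound by M1BP, in 1.03% and 0.535% (adjusted p = 0.00215). The E-box CACGTG (1.68% and 2.39%, exact test, adjusted p = 0.0103) and the repeat CACACACACA (1.13% and 2.34%, adjusted p = 4.06e-07) were less frequent at summits. GAGAGAG (exact test, adjusted p = 0.595), CAGGTAG (adjusted p = 0.212), AGTTCA (adjusted p = 0.235) and the control ACTAGTCC (adjusted p = 0.179) did not pass. Against random positions of the same GC content and distance class from a TSS, TATAAAA (18.03% and 16.9%, exact test, adjusted p = 0.251), TATCGATA (adjusted p = 0.407), CACGTG and CACACACACA (adjusted p = 0.913 each) no longer passed. GGTCACAC still did (exact test, adjusted p = 0.00430), and GAGAGAG then passed, at 3.80% and 1.73% (adjusted p = 4.18e-13). With windows of 100 bp, GGTCACAC did not pass against the flanks (exact test, adjusted p = 0.150), and GAGAGAG (adjusted p = 0.00206) and CAGGTAG (adjusted p = 0.0468) were less frequent at summits. With windows of 400 bp, CACGTG (exact test, adjusted p = 0.208) and CACACACACA (adjusted p = 0.937) did not pass, and GAGAGAG was more frequent (adjusted p = 5.43e-19). In the 500 strongest peaks GGTCACAC was in 0.2% of summit windows and 1.2% of flanks (exact test, adjusted p = 0.240). TATCGATA (1% and 0.7%, exact test, adjusted p = 0.844) and CACGTG (1.4% and 2.3%, adjusted p = 0.814) did not pass there. The ratio for CACGTG was 0.609, against 0.705 with all peaks, so its call was lost without a smaller difference.

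**Figure D4:**
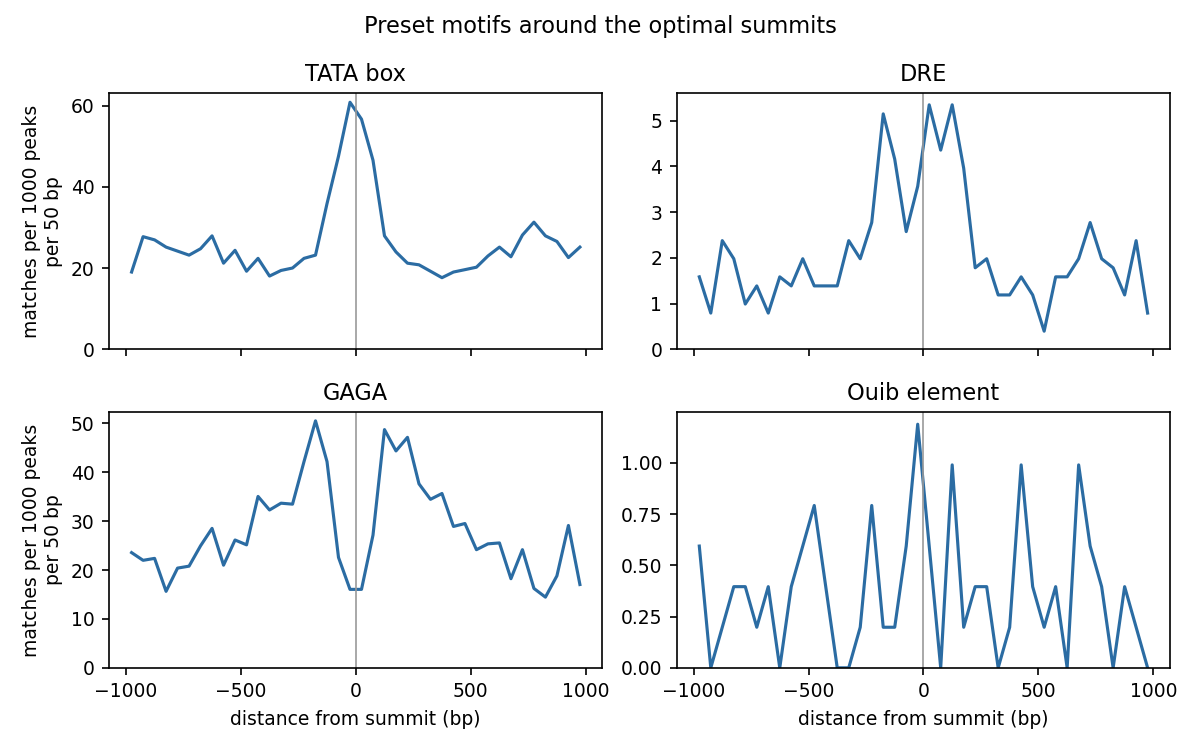
Matches of 4 preset motifs per 1000 optimal peaks in bins of 50 bp (y axis) by distance from the summit in bp (x axis). TATAAAA is most frequent at the summit, and GAGAGAG, held by 3.80% of the 200 bp summit windows, is more frequent on both sides of the summit than at it.

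Against the flanks, which were richer in GC, the search over all 8-mers gave AT-rich sequences. Of 13383 8-mers, 2338 were more frequent in windows of 100 bp at summits than in the flanks (Fisher's exact test, one-sided, adjusted over all of them). The 5 of lowest p were TATTTTAA (5.55% of summit windows, 1.79% of flanks, exact test, adjusted p = 2.92e-30), TTTAAAAA, ATTTTAAA, TTAAAAAA and ATTTAAAA. Against random positions matched on GC content, 69 passed, and 43 of these had also passed against the flanks. The 5 of lowest p were then CACTGAGA, CAGTGCAC, CACTGTGC, CAGTGTAC and ACAGTGGG, with ratios of 4.26 to 6.36. All hold CAGTG or its reverse complement CACTG. This shared stretch was seen after the search and was not tested on its own.

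The large chromosomes held peaks at densities between 33.7 and 41.6 per Mb. The X chromosome held 39.0 optimal peaks per Mb, chromosome 3L 41.6, 2L 38.2, 3R 37.5 and 2R 33.7, while the small chromosome 4 held 5.93 and no peak lay on Y. The density on X was 1.04 times that on the autosomes (permutation test, two-sided, p = 0.258).

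The authors' 2 optimal lists differed in length between genome builds, with 5048 peaks on dm6 and 4485 on dm3. No peak had an equal signal value in both lists (tolerance 1e-06). Identical coordinates were nonetheless shared by 938 peaks, 702 of them on 2L, so the lack of equal values does not make the lists unrelated. The lowest signal was 61.1 on dm6 and 66.7 on dm3, and 4530 dm6 peaks reached the lowest signal of the dm3 list.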

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

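The comparison of replicate overlap with peaks drawn from the same list was chosen after seeing the data, and the other alternatives before. Replicate overlap, the promoter share and the X to autosome ratio kept their direction and side of the threshold under every alternative run. Overlap ran from 67.9% to 80.3% and exceeded the peaks drawn from the same list by 56.6 percentage points. The promoter share ran from 20.3% with a window of 200 bp to 51.4% in the 500 strongest peaks. Where a replicate was left out below, only optimal peaks found in both others were kept, while the list and its signal still rest on all 3, so the effect of the replicate was not separated from that of the added filter. Optimal peaks numbered 3350 when found in all 3 replicates, and 3633 to 3846 with 1 replicate left out. The signal difference at promoters was 9.53 with all peaks and 11.6 to 15.2 with 1 replicate left out, and in replicate 3's own relative signal it was 0.0334 and did not pass. Lists past the threshold numbered 5, but 1 with the 500 strongest peaks, 9 with gene bodies and 3 to 7 with 1 left out. Motifs past it numbered 5, but 2 with matched random positions and 2 with the 500 strongest peaks. The 8-mers past it numbered 2338, but 69 with matched random positions, 435 with the 500 strongest peaks and, as 6-mers, 482. The cause of these changes was not tested.

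In 22 cases a difference in percentage points changed sign. With the 500 strongest peaks these were ribosomal protein genes (-1.92), neuron markers (2.02), ZAD zinc-finger genes (3.69), GAGAGAG (0.7) and GGTCACAC (-1). With a window of 5000 bp they were tRNA genes (1.21), fat body markers (3.28), muscle markers (3.28) and proteasome genes (13.3). With gene bodies they were fat body markers (2.40), muscle markers (5.74), developmental regulators (12.1) and ZAD zinc-finger genes (2.40). With peaks found in all 3 replicates they were fat body markers (0.936) and ZAD zinc-finger genes (0.936). Muscle markers ran from -3.59 to 0.867 with 1 replicate left out. With motif windows of 400 bp they were GAGAGAG (4.46), AGTTCA (-0.505) and CACACACACA (0.0396). With matched random positions they were GAGAGAG (2.07), CAGGTAG (0.109) and TATTATTTAG (-0.00991). Of these, GAGAGAG alone passed on the new side, with windows of 400 bp and with matched random positions, and the cause was not tested. No paired analysis was possible because there was 1 group.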

Other observations

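The tests of usable alignments near spok and of signal at equal strength between builds were chosen only after the result was seen, as were the counts of summits in coding sequence given next.

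The share of summits in coding sequence was lower the stronger the peaks were. Of the optimal summits, promoters included, 20 (0.396%) lay in coding sequence, against 17.2% of random positions and 4.89% of random positions weighted to the GC content of the summits. The replicates' best peaks gave 0.423% ± 0.0499 (SD, n = 3). Down the pooled list the share was 0.868% for ranks 5049 to 10000, 2.34% for 10001 to 15000, 3.94% for 15001 to 20000, 6.52% for 20001 to 25000 and 8.46% for 25001 to 30000. The weighted reference was made for the optimal summits only, so a change of GC content with rank was not separated from this rise. On both sides of the optimal summits the share in coding sequence was 3.37% at 200 bp, 11.8% at 500 bp and 19.2% at 2000 bp. The sequences of lowest p against GC-matched positions, CACTGAGA (1.21% and 0.228%), CAGTGCAC (0.971% and 0.198%) and CACTGTGC (0.971% and 0.228%), were not among the 5 of lowest p against the flanks.

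No optimal or pooled peak was found within 5 kb of the spok element. There, 100% of the 36-mers within 500 bp occurred once on the chromosomes searched, which argues against repeated sequence within those 500 bp only. A lack of usable alignments does not account for replicate 2, the only 1 of the 3 replicates with a peak within 5 kb. For replicates 1 and 3 it cannot be told apart from a lack of binding, because lists of peaks do not show coverage where no peak was called. In the 1 Mb around the element there were 0 optimal and 8 pooled peaks, against chromosome means of 37.5 and 225.8, and 3, 9 and 6 peaks in the lists of replicates 1, 2 and 3. The 36-mers cover only the sequence within 500 bp of the element, so they cannot tell why this wider stretch held few peaks. A few genes of other lists also lay far from any optimal summit, such as RpL38 at 1265.6 kb. Wide gaps were thus not particular to spok. No biological explanation was tested, and binding restricted to the prothoracic gland stays open.

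The dm6 list held 563 more optimal peaks than the dm3 list. A lower signal threshold in the dm6 list was weighed. Of its peaks, 4530 reached the lowest signal of the dm3 list, 45 more than that list holds, so most of the excess lay below that signal. The dm6 list holds every pooled peak down to its lowest signal. A lower threshold therefore restates its greater length and does not explain it, and why the cut fell lower on dm6 was not tested. The 45 are 7.99% of the excess, which argues against additional peaks of equal strength as its main source. For sequence that dm3 keeps in separate scaffolds, the test written beforehand gave 65.4% of the excess beyond the outermost dm3 peaks, but it cannot tell, because coordinates moved between the builds on 5 of the 6 chromosomes. No biological explanation applies to 2 alignments of the same libraries.

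Promoters held 33.6% of the optimal summits. GC content was weighed as a cause, and random positions weighted to the GC content of the summits lay at promoters in 11.2% of cases, which argues against it. Open chromatin was not measured here and stays open, and no biological explanation was tested.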
